A study of Mus musculus with 15 samples.

How the data were processed

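RNA purified with tagged ribosomes was measured in mice carrying the Tg(Pcp2-L10a-Egfp) transgene. This transgene places a green fluorescent protein tag on the ribosomal protein L10a under the promoter of Pcp2, a gene active in Purkinje cells. In translating ribosome affinity purification, tagged ribosomes are pulled from a tissue homogenate with beads that carry antibodies against the tag, and the RNA held by them is extracted. Per the labels, cerebella were pooled and homogenised with cycloheximide, and the purified RNA was amplified, labelled with biotin and hybridised to Affymetrix arrays. The series holds 15 arrays, 3 at each of 5 postnatal ages (P0, P7, P15, P21 and P56, in days after birth). Unpurified cerebellar RNA and RNA from the beads of mice without the transgene were not used here, so no value below is an enrichment over the tissue.

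The deposited values are log2 signals per probe set, normalized and summarised by the authors. Affymetrix Power Tools is named in the processing notes of the labels. The algorithm, its version, the background correction, the centring and the log base are not given in the sources used here. The base was taken as 2 because all values lie between 3 and 15, so each log2 change depends on that reading. The medians of the arrays were close but not identical, so the probe set values had not been quantile normalized after summarisation. No background level is given for an array, so a signal below its lower quartile (5.86 to 6.01 over the arrays) is not shown to be above background. No value was changed before the tests, no probe set was removed, and no column lay outside the 15 arrays. The file gives no depth for an array, and the number of arrays limits the precision. No scan date or batch is given for an array, so a batch shared with age cannot be told apart from age in any comparison below.

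All 22092 probe sets were tested. The annotation table, whose year is 2016, gave 1 gene symbol to 20996 probe sets and several to 91, and it did not list 1005. Of the symbols, 20959 were looked up again by Entrez number and 0 changed. For gene lists and named genes, the probe set with the highest mean over the 15 arrays stood for its gene, which left 19500 genes. Several genes of ribosomal proteins and of oxidative phosphorylation have pseudogenes of near-identical sequence, and a short probe can read both.

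Differences were tested with limma 3.58.1 in R 4.3.3, in a fit of all 15 arrays with a mean per age and no covariate (10 residual degrees of freedom per probe set, plus 6.5 from the prior). The contrasts were P56 minus P0 and the 4 steps between neighbouring ages, and the moderated F-test over the 4 steps asked whether a probe set differed between any ages. Benjamini-Hochberg adjustment ran within each contrast over all probe sets, tests were two-sided, and a probe set was called at an adjusted p under 0.05. A peak (or trough) at P7 or P15 was a probe set called higher (or lower) than both P0 and P56 with a log2 change of at least 1 against each. Errors beside a change are the standard error (SE) of the fit, and errors beside a mean are the SD over 3 arrays. Nothing beyond the labels says that the 3 arrays of an age came from separate pools of animals. If they did not, the p-values measure only the spread between these arrays. An exact two-sided permutation test of 3 against 3 arrays cannot give a p below 0.1, so all adjusted p-values rest on limma's pooled spread.

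Gene lists, 27 in all with 797 genes, were tested with camera of limma at its preset correlation of 0.01, and the adjusted p runs over the 27 lists of a contrast. Calls of list members used the adjusted p over all probe sets, and a second count was adjusted over the list alone. Camera was run again with a correlation estimated from the data, and fry, which asks whether a list moves on balance in a single direction without comparing it to other genes, was run beside it. The lists were Purkinje cell markers, Purkinje cell transcription factors, IP3 signalling, voltage-gated sodium and potassium channels, calcium channels and calcium buffers, GABA receptors and chloride transport, glutamate receptors, synaptic vesicle release, neurite growth and cytoskeleton, axon guidance ligands and receptors, cell cycle, granule cell progenitors, granule cells, astrocytes and Bergmann glia, oligodendrocyte lineage, microglia, endothelial and mural cells, meningeal and choroid plexus cells, cerebellar interneurons, red blood cells, DNA methylation and demethylation, Polycomb and H3K27 factors, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, activity-regulated early genes and inherited ataxia genes. The Purkinje cell marker and IP3 signalling lists share 11 genes. Some genes of the lists are not reported here.

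The lists, contrasts, thresholds, tests and the rule for naming genes were chosen before the data were examined. Counting how many lists differ, starting from P7 in place of P0 or from P15 in place of P21, and setting array medians to 0 for the lists were added afterwards. The rule named the 15 largest rises and the 15 largest falls from P0 to P56 among called genes whose arrays did not overlap, 6 rises and 6 falls per step, 6 genes per set of peaks or troughs and up to 4 called members per list with the largest change. It also named Pcp2, Rpl10a, and the lists of Purkinje cell markers and of DNA methylation. Predicted genes, unnamed transcripts and olfactory or vomeronasal receptors were passed over.

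The test was checked on simulated data with the spread of these arrays, in which 50 genes per size of change were shifted. Of these, 14 to 20% were called at a log2 change of 0.25, 64 to 76% at 0.5, 98 to 100% at 1 and 100% at 2, with 3 to 10 false calls among 21892 genes. Camera called the shifted list and 0 of 26 others in the simulation. The simulated genes varied independently of each other, whereas the estimated correlation of the real granule cell list, for example, was 0.48. The simulation therefore does not show how camera behaves for lists whose genes vary together.

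The alternatives were quantile normalization, array medians set to 0, array weights, a trended and robust prior, a replicate block, removal of the dimmest 50% of probe sets, a probe set per gene, another minimum change, the mean of all probe sets of a gene, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.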

Results

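The data are 15 arrays of RNA purified through ribosomes tagged in Purkinje cells, the output neurons of the cerebellar cortex. There are 3 arrays at each of P0, P7, P15, P21 and P56. The data ask how this RNA changed from the newborn to the adult mouse. Genes known from other cells gave signal too, with list means at P0 of 9.52 (granule cells) and 8.77 (endothelial and mural cells). The oligodendrocyte lineage mean was 9.90 at P21. The share of Purkinje cell RNA at each age was not measured, so a change below is not shown to belong to Purkinje cells. Values are log2 signals. The array medians were 7.91 to 7.93 at P0, 7.85 to 7.87 at P7, 7.77 to 7.81 at P15, 7.82 to 7.85 at P21 and 7.59 to 7.60 at P56. Over probe sets, the mean correlation of 2 arrays was 0.878 between P0 and P56, 0.917 between P0 and P7, 0.993 between P7 and P15, 0.994 between P15 and P21 and 0.967 between P21 and P56. Each array correlated with the others of its age at 0.995 to 0.999 on average. Of 22092 probe sets, 18018 (81.6%) differed between ages.

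**Figure D1:**
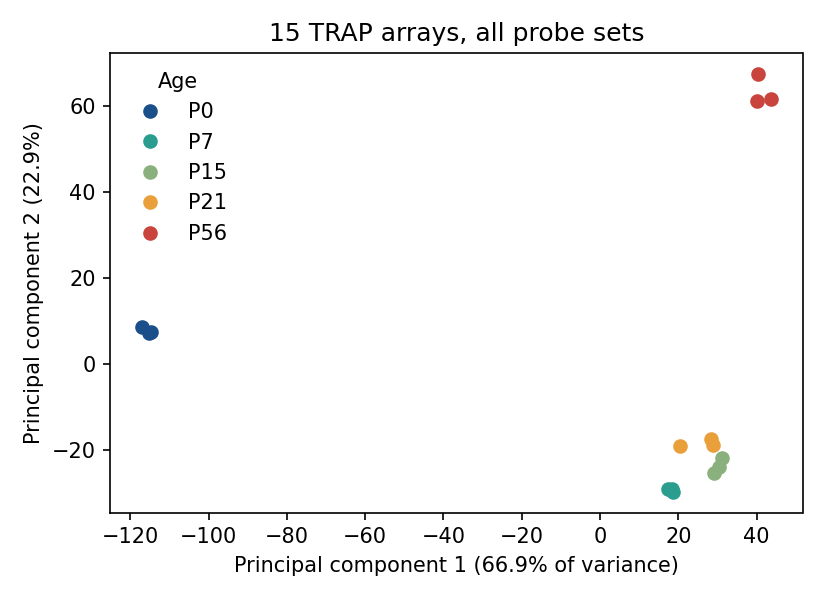
Principal components of the 15 arrays, with PC1 (66.9% of the variance) on the x axis, PC2 (22.9%) on the y axis and a point per array, coloured by age. P0 lies apart from the other ages along PC1 and P56 along PC2, while P15 and P21 lie close to each other and P21 replicate 3 lies apart from the other P21 arrays along PC1. No batch is given for the arrays, so age and a batch shared with it cannot be told apart.

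The comparison of P56 with P0 spans the series. Genes that mark Purkinje cells rose. Ppp1r17, a phosphatase inhibitor, went from 5.06 ± 0.12 to 13.37 ± 0.06 (SD, n = 3), a log2 change of 8.31 (SE 0.07, limma adjusted p 4.94e-21). Its P0 level lay below the lower quartile of the P0 arrays and is not shown to be above background, as is the case for Smpx, Sycp1, Fgf7, Gabra6, Nexn, Atp6ap1l, Scn4b, Ermn and Ier2, so the size of these rises is uncertain. Pcp2, whose promoter drives the transgene, went from 8.53 ± 0.07 to 13.71 ± 0.04, a change of 5.17 (SE 0.06). The amount of tagged ribosomes at each age was not measured and may differ with that promoter. In comparisons with P0, a change in capture therefore cannot be told apart from a change within Purkinje cells. Dcx, which encodes a microtubule protein of immature neurons, fell from 12.52 ± 0.02 to 6.24 ± 0.09, a change of −6.29 (SE 0.08). In all, 8855 probe sets were higher at P56 and 7792 lower, of which 2423 and 3535 changed by at least 1.

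Among the largest rises were the calcium buffer Pvalb (7.23, SE 0.07), the muscle protein Smpx (7.27, SE 0.09), the G protein subunit Gng13 (6.89) and Itpka (5.80), a kinase that acts on the messenger IP3. The calcium pump gene Atp2a3 rose by 5.54, the carbonic anhydrase Car7 by 5.94, the growth factor Fgf7 by 6.26 (SE 0.14) and the transcriptional repressor Hes3 by 6.37. Sycp1, known from meiotic chromosomes, rose by 7.08 (SE 0.17), the actin-binding Nexn by 5.76 and Atp6ap1l by 5.79. Cox17, a copper carrier for cytochrome c oxidase, rose by 6.04, and the small noncoding Rny1 by 5.79 (SE 0.32). Gabra6, a GABA receptor subunit known from granule cells, rose by 6.61.

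The largest falls included the surface protein Cd24a (−6.19, SE 0.19), the noncoding RNA Xist (−5.89, SE 0.11), the zinc finger gene Zfp57 (−5.88) and the sodium channel subunit Scn3b (−5.82). The transcription factors Meis2 (−5.79) and Tfap2d (−5.29), the protocadherin Pcdh11x (−5.73) and the glycine receptor subunit Glra2 (−5.55) fell as well. So did the postsynaptic scaffold Lrrc7 (−5.49), Dpysl3 of growing neurites (−5.47), the GABA receptor subunit Gabra3 (−5.47), the glutamate receptor Grm5 (−5.10), Mal2 (−5.09) and the matrix protein Tnc (−5.00). At P56, Tfap2d, Glra2, Lrrc7, Nrp1, Nhlh1, Emcn, Scn3a, Rpl12 and Uhrf1 lay under the lower quartile of the arrays, so the size of their falls is uncertain. Whether the pools of each age were alike in the sex of the animals was not tested, so the fall of Xist may not be one with age.

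Of 25 Purkinje cell markers, 19 were measured, of which 18 rose and 1 fell, with a median change of 2.83 (camera adjusted p 1.42e-09). Homer3 rose by 4.41, Slc1a6 by 3.56, Inpp5a by 3.28, Car8 by 3.10, Rgs8 by 3.04, Plcb3 by 2.86, Calb1 by 2.83, Syt2 by 2.01 and Slc32a1 by 1.69. Plcb4 rose by 1.44, Gad1 by 1.05, Aldoc by 0.95, Pcp4 by 0.55 and Dner by 0.43, and Foxp2 fell (−0.74, SE 0.09). Of 23 genes of IP3 signalling, 20 rose, 1 fell and 2 were not called, with a median of 1.57 (adjusted p 5.27e-08), and Rgs7bp (3.68) was among them. Of 23 Purkinje cell transcription factors, 16 rose, 6 fell and 1 was not called (median 0.59, adjusted p 0.0207), a call that ended with medians set to 0, and the adjusted p = 0.402 with an estimated correlation. Bhlhe41 (2.73), Lhx5 (2.52), Lhx1 (2.23) and Rora (1.99) rose most. Rpl10a, the natural gene of the tagged protein, shares sequence with pseudogenes and changed by −0.15 (SE 0.06, adjusted p 0.0226). That sign turned positive (0.17) with medians set to 0, and the call ended without P0 replicate 1 (−0.15), P0 replicate 2 (−0.14) or P56 replicate 2 (−0.14).

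Mitochondrial genes rose beside the markers. Of 71 genes of oxidative phosphorylation, 61 rose, 5 fell and 5 were not called, with a median of 1.22 (adjusted p 2.90e-13), and the adjusted p = 0.0516 with an estimated correlation. Ndufa1 rose by 4.58 (SE 0.09), Ndufb2 by 3.47, Atp5l by 3.45 and Ndufs5 by 3.22. Granule cell genes rose in 16 of 23 cases, fell in 5 and were not called in 2 (median 0.40, adjusted p 0.0143), which was lost with medians set to 0, and the adjusted p = 0.651 with an estimated correlation. Cbln3 (5.32) and Slc17a7 (3.46) rose, and the potassium channel Kcnk9 fell (−4.01).

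Genes of growing axons fell. Of 42 axon guidance genes, 1 rose, 39 fell and 2 were not called, with a median of −2.05 (adjusted p 2.90e-13). The netrin receptor Dcc (−4.95, SE 0.11), Robo1 (−4.43), Nrp1 (−4.26) and Slit1 (−4.09) fell most. Of 31 genes of neurite growth and cytoskeleton, 1 rose and 30 fell (median −1.54, adjusted p 1.90e-11), among them Marcksl1 (−4.49) and Nnat (−4.27). Of 28 glutamate receptor genes, 6 rose, 20 fell and 2 were not called (median −1.06, adjusted p 2.71e-04), and the adjusted p = 0.245 with an estimated correlation. Grin2b, a subunit of juvenile NMDA receptors, fell by 4.46 (SE 0.14), Grin3a by 4.16 and Grm3 by 3.99. Endothelial and mural genes averaged 8.77 ± 0.01 at P0 and 6.79 ± 0.06 at P56 (n = 3).

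Cell cycle genes fell in 33 of 35 cases and rose in 2 (median −1.39, adjusted p 1.25e-09). Ccna2 (−3.75), Mki67 (−3.14), Plk1 (−2.93) and Cdk1 (−2.65) fell most. Of 14 genes of granule cell progenitors, 13 fell, including Ccnd2 (−2.49), Nhlh1 (−2.01), Ccnd1 (−1.82) and Mfap4 (−1.79), and 1 was not called (median −1.36, adjusted p 2.25e-05). Cholesterol synthesis genes fell in 14 of 18 cases, rose in 2 and were not called in 2 (median −1.33, adjusted p 2.56e-04), and the adjusted p = 0.245 with an estimated correlation. Nsdhl (−2.18), Lss (−2.07), the regulator Srebf2 (−2.05) and Cyp51 (−1.99) fell most.

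Markers of 5 other kinds of cell fell, whereas granule cell genes rose and oligodendrocyte genes rose in 14 of 22 cases without a call for the list, which quantile normalization called (median 1.02). Endothelial and mural genes fell in 20 of 21 cases, with 1 not called (median −2.02, adjusted p 7.11e-09), led by Emcn (−4.15, SE 0.10), Cdh5 (−3.50, SE 0.06), Vtn (−2.69) and Itm2a (−2.64). Meningeal and choroid plexus genes fell in 16 of 17 cases, with 1 not called (median −1.46, adjusted p 5.16e-06), led by Slc6a13 (−3.43), Bgn (−3.37), Dcn (−2.98) and Islr (−2.75). Microglial genes fell in 16 of 18 cases, rose in 1 and were not called in 1 (median −0.65, adjusted p 1.25e-04), led by C1qb (−3.28), Ly86 (−2.65), C1qc (−2.50) and Laptm5 (−2.37). Astrocyte and Bergmann glia genes fell in 18 of 24 cases and rose in 6 (median −1.13, adjusted p 0.00163), and the adjusted p = 0.292 with an estimated correlation. Fabp7 (−3.18) and Aldh1l1 (−3.02) fell, and S100b rose (2.73). Cerebellar interneuron genes fell in 17 of 19 cases, rose in 1 and were not called in 1 (median −1.37, adjusted p 3.89e-06), and the adjusted p = 0.101 with an estimated correlation. Sst (−4.74), Tfap2b (−3.09), Ptprk (−2.93) and Lypd6 (−2.47) fell most.

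Among channels, GABA receptors and vesicle release genes some rose and others fell, without a call for the list. Of 30 sodium and potassium channel genes, 15 rose, 10 fell and 5 were not called, with Scn4b (5.17, SE 0.11) and Kcnab1 (4.32) up and Scn3a (−4.11) down. Of 27 genes of calcium channels and buffers, 12 rose, 13 fell and 2 were not called, with Cacna2d1 (−4.13, SE 0.11) and Cacna1h (−3.24) down. Of 18 genes of GABA receptors and chloride transport, 6 rose, 8 fell and 4 were not called, with Gabrg3 (−4.79) and Gabra5 (−4.64) down. Of 25 vesicle release genes, 10 rose, 10 fell and 5 were not called, with Doc2b up (2.52) and Rab3b (−3.07), Stx1a (−2.31) and Pclo (−2.22) down.

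The remaining lists were not called either. Of 22 oligodendrocyte lineage genes, 14 rose, 7 fell and 1 was not called. Ermn (3.61), Mobp (3.04) and Tspan2 (2.53) rose, and the precursor marker Pdgfra fell (−3.25). Of 40 ribosomal protein genes, 20 rose, 12 fell and 8 were not called, with Rps21 (3.00), Rps29 (2.50) and Rps12 (1.78) up and Rpl12 (−1.90) down, genes whose probes can also read pseudogenes. Of 29 Polycomb genes, 11 rose, 14 fell and 4 were not called, with the histone methyltransferase Ezh2 (−2.89), Pcgf6 (−2.25) and Pcgf2 (−2.12) down and Pcgf5 (1.99) up. Of 22 activity-regulated genes, 10 rose, 9 fell and 3 were not called, with Ier2 (1.96) and Arc (1.18) up and Sik1 (−2.55) and Nr4a2 (−1.62) down. Of 24 inherited ataxia genes, 7 rose, 14 fell and 3 were not called, with Kcna1 (2.73), Cacna1g (1.73) and Cacnb4 (1.58) up and Elovl4 (−2.01) down. Of 5 red blood cell genes, 3 rose and 2 fell, with Alas2 (−3.01) and Slc4a1 (−1.02) down. Median, mean and test differed in sign for calcium channels, vesicle release, red blood cells and activity-regulated genes, so no direction is given for these lists.

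For P56 against P0, 16 of 27 lists differed, 9 of them with an estimated correlation. Adjusted over the list alone, the counts of rises and falls were as above except for axon guidance, where 40 genes fell. Of called probe sets, 53.2% were higher at P56, and 70.2% with array medians set to 0, since the mean array median differed by −0.32 between P56 and P0. The median change over all probe sets was 0.085 as deposited and 0.41 with medians set to 0. With P7 in place of P0, a comparison added after the values were seen, 5601 probe sets were higher at P56 and 5 lists differed, and the Purkinje cell marker median was 0.06.

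**Figure D2:**
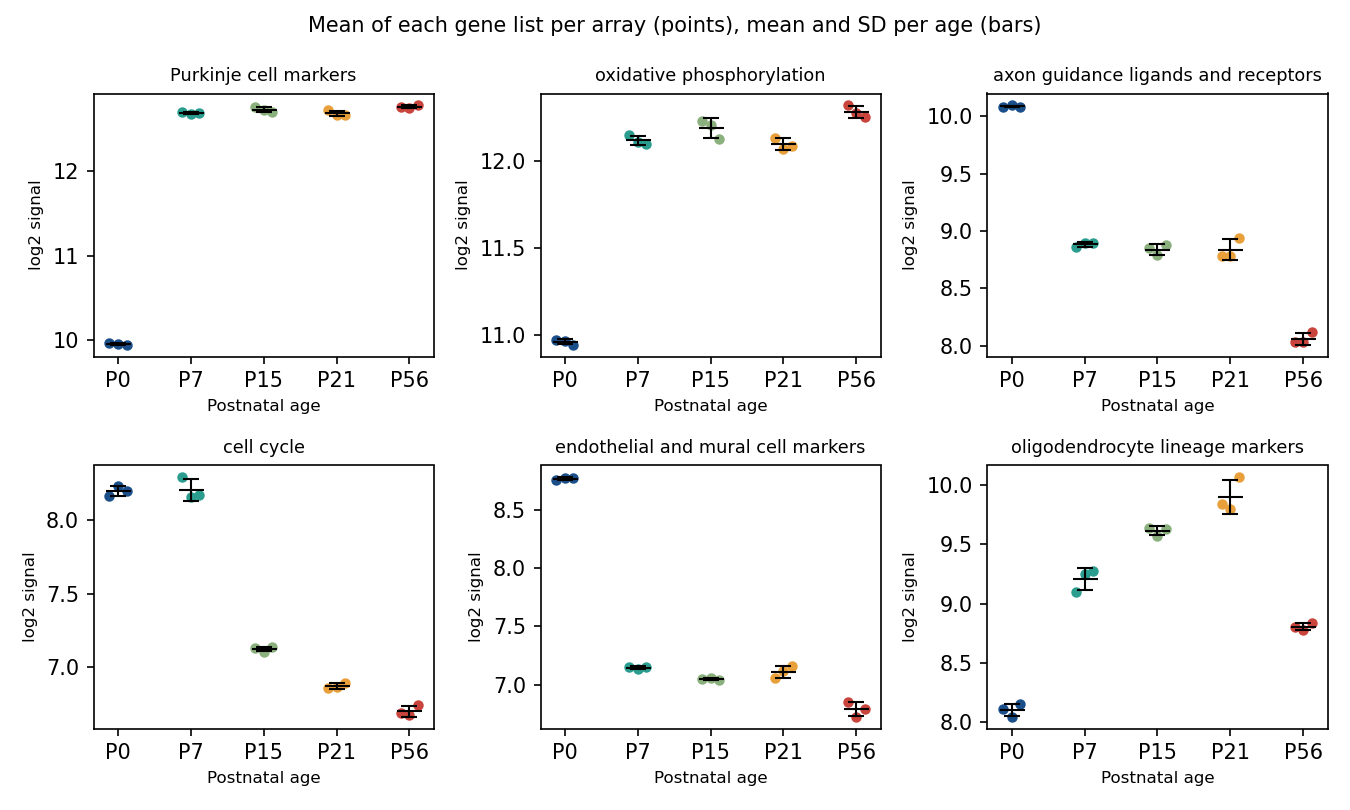
Mean log2 signal of 6 gene lists (y axis) against postnatal age (x axis), with a point per array and bars for the mean and SD of 3 arrays. The Purkinje cell marker mean went from 9.96 at P0 to 12.69 at P7 and was 12.76 at P56, while the endothelial and mural mean went from 8.77 to 7.15 and was 6.79.

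Factors of DNA methylation moved in both directions between P0 and P56. The list covers enzymes that write, read and remove methyl marks, and 22 of its 26 genes were measured, of which 8 rose, 12 fell and 2 were not called, without a call for the list (adjusted p 0.391). Tet1, an enzyme that oxidises methylcytosine, fell from 11.35 to 8.68, a change of −2.67 (SE 0.10, n = 3), and its other probe sets changed by −2.27 and −2.16. Tet2 fell from 10.03 to 7.69 (−2.34) and Tet3 from 10.15 to 8.82 (−1.33), while another Tet3 probe set changed by −0.68. The maintenance methyltransferase Dnmt1 fell from 10.59 to 9.06 (−1.53) and the methyltransferase Dnmt3a from 10.24 to 9.24. Uhrf1 (−1.32), Mbd1 (−1.26), Cxxc4 (−1.08), Uhrf2 (−0.97) and Mbd6 (−0.89) fell, Uhrf1 to a level not shown to be above background. Apex1 (−0.43) and Dnmt3b (−0.35) fell too, with calls that ended when medians were set to 0 (−0.11 and −0.02). The reader Mbd2 rose from 9.66 to 11.62 (1.95), and Gadd45a (2.57), Gadd45g (2.39), Zbtb4 (1.70), Gadd45b (1.56), Mbd4 (1.35) and Mbd3 (0.43) rose. Dnmt3l, the other gene called higher (0.62), lay below the lower quartile of the arrays at both ages and is not shown to be above background. Cxxc5 (0.11) and Smug1 (−0.06) were not called, and Smug1 turned positive with medians set to 0 (0.27) and was at 0.0016 without P56 replicate 3.

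The steps differed between these genes. Tet2 fell by 1.60 between P0 and P7, and Cxxc4 by 1.65. Tet1 fell by 0.48 between P15 and P21 and then fell by 1.97 up to P56, when Tet3 fell by 1.23 and Mbd1 by 0.86. Dnmt1 fell by 0.83 from P0 to P7 and by 0.41 from P7 to P15, rose by 0.35 from P15 to P21 and fell by 0.64 from P21 to P56. Uhrf1 fell by 1.17 and Dnmt3a by 0.60 between P7 and P15. Mbd2 rose by 1.15 from P0 to P7, by 0.38 from P7 to P15 and by 0.50 from P21 to P56, and Gadd45a by 1.55 and 1.23 in the first and last steps. Cell cycle genes, which fell with Uhrf1 between P7 and P15, averaged 8.20 at P7 and 7.12 at P15.

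**Figure D3:**
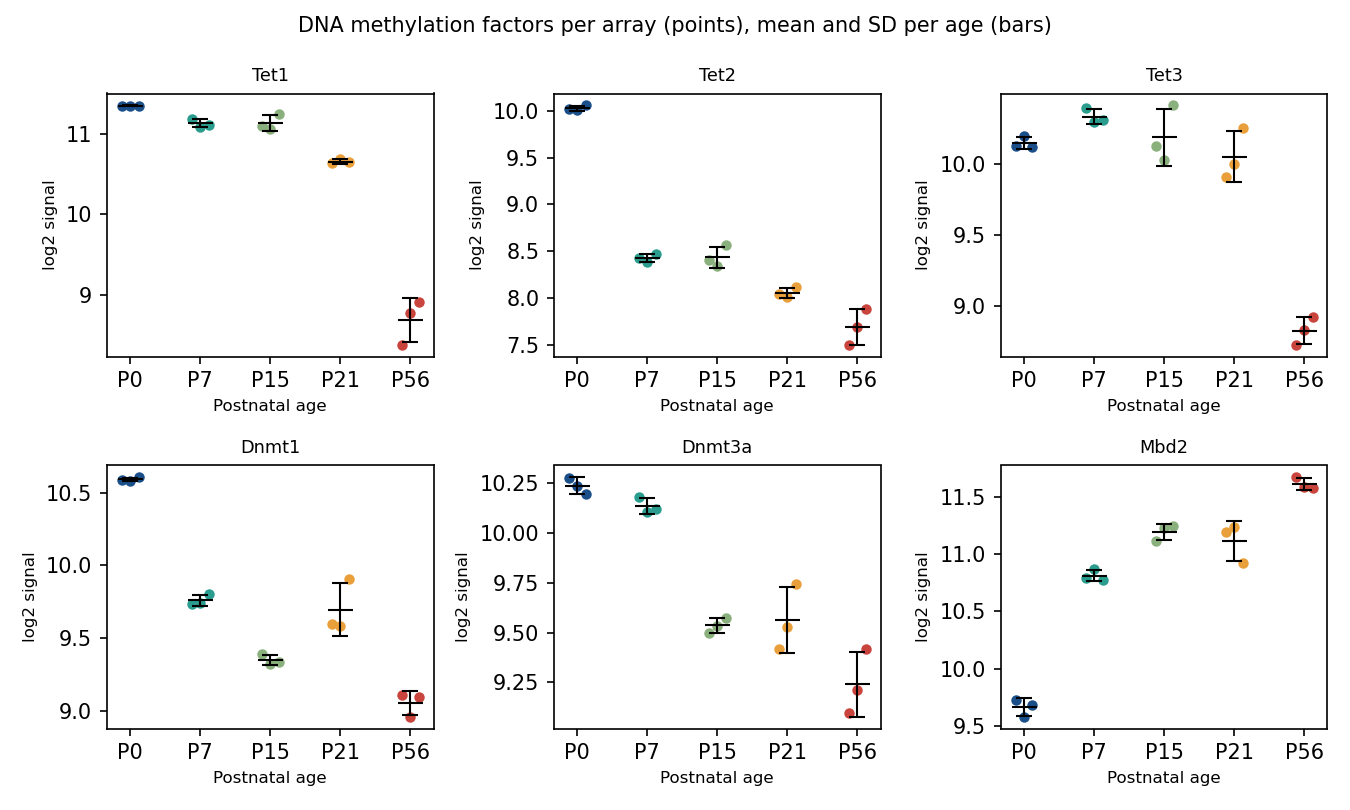
Log2 signal (y axis) of 6 factors of DNA methylation against postnatal age (x axis), with a point per array and bars for the mean and SD of 3 arrays. Tet1 went from 11.35 at P0 to 8.68 at P56, and Mbd2 from 9.66 to 11.62.

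The comparison of P7 with P0 covers the first week. Ppp1r17 rose by 7.93 (SE 0.07, n = 3), Smpx by 6.98, Pvalb by 6.97, Fgf7 by 6.84 (SE 0.14), Gng13 by 6.30 and Itpka by 6.04. Falls were led by Xist (−5.35, SE 0.11), Tfap2d (−4.64), the microRNA genes Mir377 (−4.52), Mir300 (−4.43) and Mir382 (−4.36) and the small RNA DQ267102 (−4.35, SE 0.16). The P0 levels of Ppp1r17, Smpx, Fgf7, Gabra6 and Ermn and the P7 levels of the 3 microRNA genes, Tek and Ogn are not shown to be above background. In all, 7420 probe sets were higher at P7 and 6294 lower, and 2329 and 2043 changed by at least 1.

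Of 19 Purkinje cell markers, 18 rose and 1 fell by P7 (median 2.44, adjusted p 4.42e-11). Pcp2 rose by 4.63, Homer3 by 4.39, Slc1a6 by 3.99, Inpp5a by 2.96, Car8 by 2.71 and Calb1 by 2.44. Of 23 genes of IP3 signalling, 22 rose and 1 fell (median 1.56, adjusted p 4.42e-11). Of 23 Purkinje cell transcription factors, 15 rose, 6 fell and 2 were not called (median 0.95, adjusted p 0.0121), and the adjusted p = 0.413 with an estimated correlation. Esrrb (3.16, SE 0.09), Skor2 (2.29), Rora (2.21) and Lhx5 (1.90) rose. Of 71 genes of oxidative phosphorylation, 70 rose and 1 was not called (median 1.00, adjusted p 2.93e-18), led by Ndufa1 (2.82, SE 0.09), Uqcr11 (2.82), Ndufb7 (2.32) and Atp5e (2.30).

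Of 42 axon guidance genes, 3 rose, 34 fell and 5 were not called (median −1.25, adjusted p 3.59e-11), and the adjusted p = 0.0705 with an estimated correlation. Robo1 (−3.28, SE 0.08), Slit1 (−3.21), Nrp1 (−3.01) and Dcc (−2.94) fell most. Of 31 genes of neurite growth, 1 rose, 25 fell and 5 were not called (median −0.78, adjusted p 2.26e-08), and the adjusted p = 0.0905 with an estimated correlation. Nnat (−2.47), Gap43 (−2.20) and Sox4 (−1.96) fell. Of 28 glutamate receptor genes, 8 rose, 18 fell and 2 were not called (median −0.93, adjusted p 7.36e-04), with Grin2b (−2.71) and Cacng3 (−2.68) down, and the adjusted p = 0.336 with an estimated correlation. Of 18 cholesterol synthesis genes, 3 rose, 12 fell and 3 were not called (median −0.29, adjusted p 0.0206), with Cyp51 (−1.46), Fdft1 (−1.06) and Srebf2 (−0.95) down and Pmvk (1.63) up, and the adjusted p = 0.525 with an estimated correlation.

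Markers of other cell types moved in both directions with these groups. Endothelial and mural genes fell in 20 of 21 cases, with 1 not called (median −1.74, adjusted p 3.59e-11), including Cdh5 (−3.24, SE 0.06), Emcn (−2.86), Vtn (−2.34) and Tek (−2.08). Meningeal and choroid plexus genes fell in 16 of 17 cases, with 1 not called (median −1.46, adjusted p 1.04e-07), including Slc6a13 (−3.03), Bgn (−2.53), Dcn (−2.40) and Ogn (−2.12). Microglial genes fell in 14 of 18 cases, rose in 1 and were not called in 3 (median −0.93, adjusted p 1.69e-06), including C1qb (−2.91), C1qc (−2.61) and Ly86 (−2.36). Astrocyte and Bergmann glia genes fell in 18 of 24 cases, rose in 3 and were not called in 3 (median −0.80, adjusted p 8.75e-05), and the adjusted p = 0.221 with an estimated correlation. Gja1 (−2.31), Tnc (−2.28) and Apoe (−2.19) fell, and Hopx (3.07) rose. Cerebellar interneuron genes fell in 14 of 19 cases, rose in 2 and were not called in 3 (median −1.33, adjusted p 1.04e-05), and the adjusted p = 0.148 with an estimated correlation. Tfap2b (−3.35), Sst (−2.78) and Nxph1 (−2.47) fell, and Prkcd (2.95) rose.

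Oligodendrocyte lineage genes rose in 15 of 22 cases, fell in 6 and were not called in 1 (median 1.48, adjusted p 0.00599), and the adjusted p = 0.513 with an estimated correlation. The myelin genes Mog (3.34, SE 0.13), Mobp (3.27), Mal (2.61) and Ermn (2.57) led them. Granule cell genes rose in 13 of 23 cases, fell in 5 and were not called in 5 (median 0.49, adjusted p 0.0484), a call that quantile normalization, medians set to 0 and a replicate block each ended, and the adjusted p = 0.733 with an estimated correlation. Gabra6 (5.65), Cbln3 (4.38), Slc17a7 (3.07) and Gabrd (2.35) rose.

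Between P0 and P7, 15 of 27 lists differed, 6 of them with an estimated correlation, and 12 did not. Adjusted over the list alone, the counts were as above for the lists named, except that 16 transcription factors rose, 6 granule cell genes fell and 15 microglial genes fell. Of called probe sets, 54.1% were higher at P7 (59.5% with medians set to 0).

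Between P7 and P15 cell cycle genes fell. Ccna2 (−2.21, SE 0.14, n = 3), Plk1 (−2.02), Top2a (−2.00) and Mki67 (−1.97) led them, and of 35 genes of the list 1 rose, 31 fell and 3 were not called (median −1.16, adjusted p 1.92e-35). The largest falls of the step also included Islr2 (−2.88, SE 0.12), the troponin Tnnt1 (−2.64), the integrin Itga5 (−2.37), Zmat4 (−2.15) and the actin bundler Fscn1 (−2.12). The noncoding Mir670hg (1.36, SE 0.12), Fam107a (1.28), Ly96 (1.24), the syndecan Sdc2 (1.12), Cox7a1 (1.11) and Cstad (1.09) rose most. In all, 2296 probe sets were higher at P15 and 3009 lower, and 16 and 162 changed by at least 1. Without P7 replicate 1 the higher count was 1524.

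Of 14 genes of granule cell progenitors, 1 rose, 9 fell and 4 were not called (median −0.78, adjusted p 1.67e-09), with Ccnd2 (−1.76, SE 0.07), Mycn (−1.70), Atoh1 (−1.66) and Nhlh1 (−1.63) down. Of 31 neurite growth genes, 2 rose, 20 fell and 9 were not called (median −0.47, adjusted p 3.54e-11), and the adjusted p = 0.101 with an estimated correlation. Marcksl1 (−1.31), Tubb2b (−1.30), Dpysl3 (−1.28) and Dcx (−1.10) fell. Of 40 ribosomal protein genes, 26 fell and 14 were not called (median −0.29, adjusted p 9.64e-11), and the adjusted p = 0.244 with an estimated correlation. Rps4x (−0.91), Rps3 (−0.83) and Rps19 (−0.81) fell.

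Calcium and channel genes had more rises than falls. Of 27 genes of calcium channels and buffers, 13 rose, 2 fell and 12 were not called (median 0.22, adjusted p 1.44e-05), and the adjusted p = 0.269 with an estimated correlation. Calb2 (0.88, SE 0.10), the exchangers Slc8a1 (0.67) and Slc8a2 (0.58) and the pump Atp2b3 (0.57) rose most. Of 30 sodium and potassium channel genes, 14 rose, 5 fell and 11 were not called (median 0.20, adjusted p 0.00164), and the adjusted p = 0.307 with an estimated correlation. Scn4b rose by 0.70 (SE 0.11), and Kcnq5 (−0.64), Scn3a (−0.59, to a level not shown to be above background) and Kcnq3 (−0.56) fell. Granule cell genes rose in 16 of 23 cases, fell in 1 and were not called in 6 (median 0.33, adjusted p 2.97e-09), and the adjusted p = 0.276 with an estimated correlation. Etv1 (0.98), Calb2 (0.88), Olfm3 (0.86) and Gabra6 (0.84) rose. Oligodendrocyte lineage genes rose in 14 of 22 cases, fell in 1 and were not called in 7 (median 0.38, adjusted p 1.91e-08), and the adjusted p = 0.244 with an estimated correlation. Ermn (0.90), Mobp (0.84), Opalin (0.84) and Mog (0.82) rose. Of 19 Purkinje cell markers, 1 rose, 2 fell and 16 were not called.

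Between P7 and P15, 8 of 27 lists differed, 2 of them with an estimated correlation. Adjusted over the list alone, 16 channel, 16 calcium, 18 granule cell and 15 oligodendrocyte genes rose, and 32 cell cycle, 10 progenitor and 31 ribosomal protein genes fell. Of called probe sets, 43.3% were higher at P15, and 62.2% with medians set to 0 (3583 higher, 2178 lower).

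Between P15 and P21 the largest rises were of Lamp5 (1.90, SE 0.12, n = 3), the neuropeptide gene Tac1 (1.65, SE 0.18), the imprinted Peg10 (1.55), Tent5c (1.54), Camkv (1.48) and the glycine receptor subunit Glra1 (1.44). Dcx (−2.05, SE 0.08), Nhlh1 (−1.60), Yeats2 (−1.36), Zfp57 (−1.32), Marcksl1 (−1.25) and Ccna2 (−1.19) fell most. In all, 2322 probe sets were higher at P21 and 1581 lower, and 71 and 17 changed by at least 1. The lower count was 990 without P15 replicate 3 and 994 without P15 replicate 1. Tph2 (1.19), Slc17a6 (0.97), Hoxa5 (0.58) and Hoxb5 (0.56, from a P15 level not shown to be above background), known from the brainstem and spinal cord and chosen after their values were seen, were also higher at P21.

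Of 22 activity-regulated genes, 8 rose and 14 were not called (median 0.15, adjusted p 8.14e-05), and the adjusted p = 0.148 with an estimated correlation. Nr4a3 (1.13), Npas4 (1.07), Dusp1 (0.94) and Nr4a1 (0.87) rose. Of 25 vesicle release genes, 8 rose and 17 were not called (median 0.16, adjusted p 2.69e-04), and the adjusted p = 0.279 with an estimated correlation. Sv2c (1.37, SE 0.12) and Vamp1 (0.29) rose. Oligodendrocyte lineage genes rose in 11 of 22 cases and were not called in 11 (median 0.31, adjusted p 8.14e-05), with Aspa (1.12, SE 0.14), Mal (0.77) and Fa2h (0.46) up, and the adjusted p = 0.317 with an estimated correlation. Microglial genes rose in 4 of 18 cases and were not called in 14 (median 0.20, adjusted p 0.00472), with Laptm5 (0.51) up, and the adjusted p = 0.254 with an estimated correlation. Of the 4, Tyrobp (0.34) and Ctss (0.27) lost their call without P21 replicate 3, and Tyrobp (0.33) and C1qa (0.30) without P15 replicate 3. Meningeal and choroid plexus genes rose in 3 of 17 cases and were not called in 14 (median 0.17, adjusted p 0.0156), with Aldh1a2 (0.53) and Fmod (0.43) up. That list lost its call without P21 replicate 3 (median 0.19), and the adjusted p = 0.317 with an estimated correlation. Cerebellar interneuron genes rose in 7 of 19 cases, fell in 2 and were not called in 10 (median 0.18, adjusted p 0.0325), with Sst (1.30), Slc6a5 (1.02) and Npy (0.71) up and Neto2 (−0.75) down. That call ended without P15 replicate 2 (median 0.14), without P21 replicate 3 (0.12) and with quantile normalization (0.13), and the adjusted p = 0.559 with an estimated correlation.

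Among proliferation and neurite genes, falls outnumbered rises. Of 35 cell cycle genes, 1 rose, 14 fell and 20 were not called (median −0.25, adjusted p 2.21e-06), with Mki67 (−0.97, to a level not shown to be above background), Aurkb (−0.60) and Ube2c (−0.56) down, and the adjusted p = 0.127 with an estimated correlation. Of 14 progenitor genes, 1 rose, 7 fell and 6 were not called (median −0.20, adjusted p 8.40e-04), with Mfap4 (−0.74), Sfrp1 (−0.61) and Barhl1 (−0.56) down, and the adjusted p = 0.127 with an estimated correlation. Of 31 neurite growth genes, 2 rose, 9 fell and 20 were not called (median −0.14, adjusted p 6.34e-06), with Marcks (−1.18) down and Fez1 (1.06) up, and the adjusted p = 0.267 with an estimated correlation. Of 71 genes of oxidative phosphorylation, 2 rose, 9 fell and 60 were not called (median −0.11, adjusted p 1.21e-04), with Ndufs5 (−0.56), Ndufb2 (−0.33) and Ndufs4 (−0.32) down, and the adjusted p = 0.420 with an estimated correlation. Of 40 ribosomal protein genes, 8 fell and 32 were not called (median −0.10, adjusted p 8.40e-04), with Rpl23 (−0.45) and Rps28 (−0.38) down, and the adjusted p = 0.559 with an estimated correlation. Of 19 Purkinje cell markers, 1 rose, 1 fell and 17 were not called.

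Between P15 and P21, 11 of 27 lists differed by camera. With an estimated correlation 0 did, 5 had an unadjusted p under 0.05, and fry called 13. Adjusted over the list alone, 9 activity-regulated, 10 vesicle, 4 meningeal and 10 interneuron genes rose, and 18 cell cycle, 7 progenitor, 12 neurite and 6 oxidative phosphorylation genes fell. Of called probe sets, 59.5% were higher at P21, and 45.9% with medians set to 0 (1885 higher, 2226 lower).

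Between P21 and P56 the largest rises were of small structured RNAs, namely Rny1 (7.14, SE 0.32, n = 3), Snord22 (4.74, SE 0.17), Snord61 (4.47, SE 0.37), n-R5s136 (3.91) and Snord87 (3.53), and of Usp17ld (3.96). Glra1 (−3.87, SE 0.13), the phospholipase Pla2g5 (−3.65), Lamp5 (−3.60), Lrrc7 (−3.19), Sst (−3.16) and Tac1 (−3.11) fell most. The P21 levels of Rny1, Snord22, Snord61 and Snord87 and the P56 levels of Lrrc7 and Tac1 are not shown to be above background, so the size of these changes is uncertain. Hindbrain genes were lower at P56 beside them, 11 of 19 in a list written later and all 8 chosen after their values were seen (median −2.70). In all, 4893 probe sets were higher at P56 and 7571 lower, and 430 and 1240 changed by at least 1. Of 19 Purkinje cell markers, 8 rose, 4 fell and 7 were not called, with Slc32a1 (0.55), Pcp2 (0.49, SE 0.06), Calb1 (0.47), Car8 (0.35), Pcp4 (0.30) and Inpp5a (0.30) up and Syt2 (−0.53) and Dner (−0.44) down.

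Of 42 axon guidance genes, 37 fell and 5 were not called (median −0.68, adjusted p 1.78e-09), with Sema5a (−1.80, SE 0.09), Plxna2 (−1.56), Slit2 (−1.54) and Plxna1 (−1.52) down, and the adjusted p = 0.403 with an estimated correlation. Of 28 glutamate receptor genes, 1 rose, 20 fell and 7 were not called (median −0.59, adjusted p 7.51e-05), with Grm5 (−2.17), Grin3a (−1.59), Grid1 (−1.49) and Cacng3 (−1.37) down. Of 31 neurite growth genes, 3 rose, 22 fell and 6 were not called (median −0.54, adjusted p 6.30e-04), with Dpysl3 (−2.12), Fez1 (−1.84), Dcx (−1.30) and Basp1 (−1.29) down. Of 30 sodium and potassium channel genes, 2 rose, 19 fell and 9 were not called (median −0.24, adjusted p 0.00640), with Scn3b (−2.24, SE 0.07), Kcnc2 (−1.83), Scn2a (−1.83) and Kcnq5 (−1.04) down. Cerebellar interneuron genes fell in 13 of 19 cases and were not called in 6 (median −0.59, adjusted p 0.00134), with Slc6a5 (−2.09), Eomes (−1.88) and Lypd6 (−1.48) down. For each of these 4 lists after axon guidance the adjusted p = 0.403 with an estimated correlation.

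Oligodendrocyte lineage genes fell in 19 of 22 cases and were not called in 3 (median −1.11, adjusted p 6.97e-08), with Mog (−2.12), Fa2h (−2.08), Enpp6 (−1.67) and Mbp (−1.58) down. Cholesterol synthesis genes fell beside them in 15 of 18 cases, rose in 1 and were not called in 2 (median −0.76, adjusted p 8.30e-05), with Fdps (−2.04), Lss (−1.66), Nsdhl (−1.46) and Sqle (−1.43) down. Of 40 ribosomal protein genes, 26 rose, 7 fell and 7 were not called (median 0.39, adjusted p 4.15e-07), with Rps12 (2.59, SE 0.09), Rps21 (2.54), Rps29 (1.96) and Rps3a1 (1.52) up. Of 24 ataxia genes, 3 rose, 16 fell and 5 were not called (median −0.37, adjusted p 0.0172), a call that ended with quantile normalization (−0.26), with Elovl4 (−1.52), Atxn10 (−1.04), Atxn3 (−0.95) and Nop56 (−0.66) down. For each of these 4 lists the adjusted p = 0.403 with an estimated correlation.

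Of 27 genes of calcium channels and buffers, 4 rose, 20 fell and 3 were not called (median −0.42, adjusted p 0.00491), with Cacna2d1 (−1.71), Cacna1e (−1.59), Cacna1b (−1.49) and Cacna1d (−1.23) down, and the adjusted p = 0.440 with an estimated correlation. Of 18 genes of GABA receptors and chloride transport, 2 rose, 12 fell and 4 were not called (median −0.28, adjusted p 0.0186), with Gabra3 (−2.88), Gabra2 (−2.38), Gabrg3 (−1.86) and Gabrg1 (−1.59) down, and the adjusted p = 0.483 with an estimated correlation. Of 71 genes of oxidative phosphorylation, 32 rose, 20 fell and 19 were not called (median 0.11, adjusted p 0.00236), with Ndufs5 (1.84), Ndufa12 (1.69), Ndufa1 (1.53) and Atp5l (1.23) up, and the adjusted p = 0.478 with an estimated correlation. With P15 in place of P21 that median was −0.03.

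Between P21 and P56, 12 of 27 lists differed by camera. With an estimated correlation 0 did, 2 had an unadjusted p under 0.05, and fry called 26. Adjusted over the list alone, 27 ribosomal protein and 32 oxidative phosphorylation genes rose, and 21 channel, 21 calcium, 16 cholesterol and 17 ataxia genes fell. Of called probe sets, 39.3% were higher at P56, and 69.1% with medians set to 0 (11028 higher, 4935 lower), which takes the change of the mean median, −0.23, out of every difference. The median change over all probe sets was −0.027 as deposited and 0.21 with medians set to 0.

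Peaks and troughs compare the juvenile ages with both ends of the series. At P7, 210 probe sets peaked and 114 were in a trough, and at P15 238 and 112. Quantile normalization gave 124 peaks at P7 and 144 at P15, medians set to 0 gave 132 peaks at P7, and 1 probe set per gene gave 24 troughs at P7 and 22 at P15. Pla2g5 had means of 6.93, 10.51, 10.92, 10.74 and 7.10 in order of age (n = 3 each), and the peptide gene Uts2 6.13, 10.89, 10.73, 10.00 and 7.52. Tnnt1 (5.90, 9.16, 6.52, 6.19 and 6.52) and Arid3c (7.07, 9.38, 7.40, 7.16 and 6.93) peaked at P7 and not at P15. The other genes named met the rule at both P7 and P15, Pla2g5 and Uts2 included. They were the chaperone gene Hspb1 (8.29, 11.57, 10.10, 9.04 and 9.08), the crosslinking enzyme gene Lox (7.40, 9.29, 9.70, 8.77 and 6.72), Dct (5.40, 7.93, 8.21, 7.73 and 6.05) the calcium-binding Ocm (5.58, 8.83, 9.19, 8.36 and 7.06) and Gtsf2 (4.56, 9.49, 9.39, 9.05 and 7.24). The P0 levels of Tnnt1, Dct, Ocm and Gtsf2 are not shown to be above background.

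Troughs were largely of probe sets without a single symbol (81 of 114 at P7 and 82 of 112 at P15, against 1 of 210 and 9 of 238 peaks). Small RNAs were among the named ones, and the levels of Snord82, Snord47, Rny1 and Snord14e at P7 and P15 are not shown to be above background. At P7, Snord82 differed from P0 by −4.07 and from P56 by −2.66, Rny3 by −2.15 and −3.10, Snord47 by −2.18 and −2.11, Rny1 by −1.97 and −7.76, Snord104 by −2.07 and −1.89, and Snord14e by −2.46 and −1.70. At P15 the cell cycle gene Pttg1 differed from P0 by −1.64 and from P56 by −2.60. Independent lists of the observed sizes would share 159 and 41.6 probe sets at P7 and 138 and 44.1 at P15, and simulated arrays without an effect gave 0 in 20 runs. Those simulated arrays had no difference between ages, so they cannot say how many probe sets overlap where many differ between ages.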

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

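The comparisons that start from P7 or P15 in place of P0 or P21, the counts of gene lists, and medians set to 0 for the lists were chosen after the results were seen. Adding 16 before a logarithm was not run, because the values are already logarithms. In the steps, only called genes and lists were recomputed, since the sign of a value near 0 turns easily.

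Quantile normalization gave 124 peaks at P7 and 144 at P15, in place of 210 and 238, and the cause was not tested. It turned the Polycomb list median for P56 minus P0 to 0.069. Of 502 gene results, 495 kept their call and direction and 7 lost the call. Of 73 list results, 68 kept both, 3 lost the call and 1, the oligodendrocyte list for P56 minus P0, gained it (1.02).

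Setting array medians to 0 takes the difference between medians out of every change, which raises each P56 value against P0 and P21. The median change over all probe sets went from 0.085 to 0.41 for P56 minus P0 and from −0.027 to 0.21 for P56 minus P21. The setting thus moved the middle of these changes away from 0, and a call or sign that turned under it may reflect that shift. It gave 13631 probe sets higher at P56 than at P0, 11028 higher and 4935 lower at P56 than at P21, 3583 higher at P15 than at P7 and 132 peaks at P7. For P56 minus P0 the median turned to 0.29 for calcium channels and buffers, 0.24 for GABA receptors, 0.26 for Polycomb factors and 0.11 for inherited ataxia genes, and the change of Rpl10a to 0.17 and of Smug1 to 0.27. Plcb3 turned to 0.094 for P56 minus P21. Of 502 gene results, 488 kept call and direction.

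Array weights gave 3551 probe sets higher at P15 than at P7, and 498 of 502 gene results kept call and direction, and the cause was not tested. A trended and robust prior left all 502 as they were.

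Removing the dimmest 50% of probe sets tests fewer of them, and 10830 differed between ages. It left 4708 higher and 4982 lower at P56 than at P0, 3532 lower at P7 than at P0 and 2295 higher at P56 than at P21. With 1 probe set per gene, which drops the probe sets without a single symbol, troughs numbered 24 at P7 and 22 at P15.

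A minimum log2 change of 1 gave 2423 higher and 3535 lower for P56 against P0, 2329 and 2043 for P7 against P0, 16 and 162 for P15 against P7, 71 and 17 for P21 against P15, and 430 and 1240 for P56 against P21. Without a minimum change, P7 had 3078 peaks and 1133 troughs and P15 had 3097 and 1178. Both follow from the size demanded.

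With P7 in place of P0, 5601 probe sets were higher at P56 and 5 lists differed. The medians turned to −0.15 for Purkinje cell transcription factors, −0.0098 for sodium and potassium channels, −0.063 for vesicle release, −0.46 for oligodendrocyte genes and −0.10 for activity-regulated genes, and 11 lists lost their call, these transcription factors, the Purkinje cell markers (0.06) and oxidative phosphorylation (0.06) among them. With P15 in place of P21, the oxidative phosphorylation median turned to −0.026.

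With a correlation estimated by camera, 9 lists differed for P56 minus P0, 6 for P7 minus P0, 2 for P15 minus P7, 0 for P21 minus P15 (5 at an unadjusted p under 0.05) and 0 for P56 minus P21 (2 unadjusted). Fry, which does not compare a list with other genes, called 25, 24, 13, 13 and 26. The preset correlation was lower than the estimated one for each list in each contrast, which widens the estimated test.

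The replicate numbers were not taken to pair the arrays: over 30 pairs of arrays with the same number, the mean correlation of residuals was 0.00167 (−0.31 to 0.45), 5 were over 0.1, and 6 of 15 arrays matched their own number best. Between P15 and P21 it was 0.33, 0.45 and 0.016 for numbers 1 to 3 (mean 0.27, against −0.13 for other numbers), and the cause was not tested. With a replicate block, 17905 probe sets differed between ages, the P7 minus P0 call of granule cell genes was lost (0.49), and so was that of Plcb3 for P56 minus P21 (−0.14). Each count stayed within 1.5 times the main value.

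Leaving out an array gave 1524 to 2002 probe sets higher at P15 than at P7 (lowest without P7 replicate 1) and 990 to 1644 lower at P21 than at P15 (lowest without P15 replicate 3, and 994 without P15 replicate 1). The P56 minus P0 median ran from −0.094 to 0.011 for calcium channels (positive without P0 replicate 2), from −0.15 to 0.013 for Polycomb factors (positive without P0 replicate 3) and from −0.032 to 0.079 for vesicle release (negative without P56 replicate 3), and the change of Smug1 from −0.089 to 0.0016 (positive without P56 replicate 3). None of these 4 was called at first. Over these fits, 2955 gene results kept call and direction, 56 lost the call and 1 turned, and 432 list results kept both, 3 lost the call and 3 turned. The causes were not tested.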

Other observations

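Of the tests here, the further vascular, immune and connective tissue genes, the further hindbrain genes and the imprinted genes were written down before their values were seen. The tests of the oligodendrocyte list, of scaling, of gene length and of a single P21 array were chosen only after the result was seen.

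Imprinted genes, which are transcribed from the copy of a single parent, were looked at as a group after Peg10, Meg3, Rian and Nnat had been seen to fall, and these were left out of the test. Of 35 further imprinted genes, 24 were measured, and 2 of the 35 stand on another list. Whether the further genes are regulated together with each other or with those seen first was not looked at, so they are not shown to be independent. Between P0 and P56, 17 fell, 3 rose and 4 were not called, with a median of −1.64. Mest (−5.00), Zim1 (−3.72), Dlk1 (−3.07), Ndn (−2.23) and Peg3 (−1.74) fell, and Commd1 (1.73), Nap1l5 (0.66) and Phlda2 (0.48) rose. By step, 18 fell and 2 rose from P0 to P7, and 16 fell and 3 rose from P21 to P56. Between these, 2 fell and 6 rose from P7 to P15, and 1 fell and 7 rose from P15 to P21. The group may fall with postnatal age in the first and last steps, as a hypothesis. What cells the fall belongs to was not tested.

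Small structured RNAs, 60 genes of small nucleolar, Y and related RNAs, fell in 50 cases, rose in 3 and were not called in 7 between P0 and P7 (median −1.09). Between P21 and P56, 42 rose, 4 fell and 14 were not called (median 0.51), and between P0 and P56, 21 rose and 32 fell. The group was not among the lists fixed beforehand and holds small RNAs named above, such as Rny1 and Snord22, so its counts are no separate test of them. Like Xist, these RNAs are noncoding, so their signal is not shown to come from RNA held by tagged ribosomes. Xist was at 11.89 at P0, 6.55 at P7, 6.22 at P15 and 6.09 at P21. The sex of the animals in the pools was not compared, so a difference in sex between P0 and the later ages stays open for Xist.

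Endothelial, meningeal and microglial genes fell together between P0 and P7, and of 21 further genes of vascular, immune and connective tissue cells 19 fell and 2 (Ptprc and Col5a1) were not called (median −1.24), with Fn1 at 10.91, Cd34 at 9.83 and Eng at 9.81 at P0. RNA of such cells carried through the purification in a larger share at P0 may account for this. How much of it the antibody beads removed was not measured, and which of the 21 genes Purkinje cells express was not tested. A dilution of Purkinje cell RNA that raises all other cell types alike, as the sole cause, is argued against by the oligodendrocyte list (median 1.48, SD of its genes 1.65), which moved apart from the endothelial list (−1.74, SD 0.75). A change of the oligodendrocytes themselves stays open, and since astrocyte (−0.80) and interneuron (−1.33) genes fell, dilution as a part of the cause stays open too. Scaling is argued against by the smallest median fall of the 3 lists under any of 3 scalings, −0.76, and a change of the cells with age stays open, untested.

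The trend with gene length was looked at in 9604 protein-coding genes whose mean signal lay above the median of all genes. Among them, long genes fell more than short ones from P0 to P56. By step, the correlation of the change with gene length (rho) was −0.25 from P0 to P7 and −0.13 from P21 to P56. It was 0.039 from P7 to P15 and 0.089 from P15 to P21. Lists were matched on length for P0 to P56 only. Over 9604 genes the median change from P0 to P56 was 0.35 in the shortest of 4 length classes (up to 10 kb), then −0.035 and −0.29, and −0.66 in the longest, with a correlation across genes of −0.22 (rho), and genes are not independent replicates. Random lists matched on gene length and mean signal had a median of −0.60 for axon guidance (list −2.05), 0.089 for neurite growth (list −1.54), −0.37 for glutamate receptors (list −1.06) and 0.30 for oxidative phosphorylation (list 1.22). Each list lay outside the range of 95% of its random lists, so a length trend is unlikely to be the whole cause. It may account for part of the axon guidance, glutamate receptor and oxidative phosphorylation changes, whose random lists had medians of the same sign, although the range for glutamate receptors (−0.90 to 0.16) includes 0. Development of the cells stays open, untested.

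Of genes known from hindbrain neurons, 8 seen at first (Sst, Tac1, Glra1, Lamp5, Tph2, Slc17a6, Hoxb5 and Hoxa5) were higher at P21 than at P15 with a median rise of 1.25. Sst also stands on the cerebellar interneuron list, and the 8 genes are not shown to be particular to the hindbrain. Without the P21 array in which the 8 genes had the highest mean, the median rise was 1.15, so that array alone does not carry it. Of 19 further hindbrain genes measured out of 20, 8 were higher, including Ddc (1.43, to 8.49), Slc18a2 (1.14, to 8.12) and Slc6a4 (0.63, to 8.21), and 11 were not called, namely Phox2a and all 10 further Hox genes (median of the 19, 0.20, and 0.38 for the 14 above the dimmest 25% of probe sets). From P0 to P7, 15 of the 19 fell and 1 rose (median −0.86), and at P0 Gata3 (10.65), Slc6a4 (9.62) and Slc18a2 (9.32) had means above those at P21, which did not hold for Ddc (8.42 at P0), Glra1 and Tph2. From P21 to P56, 11 of the 19 fell and 2 rose. From P0 to P56, 13 fell and 2 rose (median −1.02), beside the fall of the cerebellar interneuron list. Hindbrain tissue left on the dissected P21 cerebella is a candidate source, and how much of its RNA the beads removed was not measured. The 10 further Hox genes were not called. Of these, Hoxa2 (5.46 at P15 and 5.55 at P21), Hoxa3 (5.16 and 5.28) and Hoxc4 (5.43 and 5.63) lay below the lower quartile of the arrays. A rise could be missed at such levels, so the Hox genes do not decide on this source. Whether the P0 levels share that source was not tested, and a change of tagged cells with age stays open.

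Other splits of the arrays show how far chance can be set aside. For the difference between any ages, 1 of 100 splits, the real, gave as many as 18018 probe sets, and the highest other gave 8162. A random assignment of single arrays to ages is thus unlikely to give the real count. The splits treat the arrays as independent, so chance in which pools of animals stood for an age was not tested. Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The real counts were 8855 and 7792 for P56 against P0, 7420 and 6294 for P7, 2296 and 3009 for P15, 2322 and 1581 for P21 and 4893 and 7571 for P56 against P21, and the highest other count was 0 in each. For lists, 2 of 10 splits reached the real 16 for P56 minus P0 (highest other 16), 1 the 15 for P7 minus P0 (highest other 14), 6 the 8 for P15 minus P7 (highest other 11), 5 the 11 for P21 minus P15 (highest other 15) and 5 the 12 for P56 minus P21 (highest other 15). Camera with its preset correlation thus called as many lists or more between some mixed groups as between the ages in all but the P7 step. Each mixed group kept 2 of the 3 arrays of its age, so part of the age difference remained in these splits. Lists called there are therefore not shown to be false calls, and the splits do not decide on the lists.

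For peaks at P7, 7 of 100 splits gave 210 or more (highest other 2267) and for troughs 7 gave 114 or more (highest other 1981). At P15, 4 of 100 gave 238 peaks or more (highest other 2583) and 4 gave 112 troughs or more (highest other 2113). The splits with several times the real count mix ages, which points to a structure of the samples by age. The shares therefore do not decide on chance and do not set P15 apart from P7. Simulated arrays without an effect gave 0 peaks or troughs in each of 20 runs. Hardly any probe set can be called where the ages do not differ, so the simulation does not decide on chance either.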
